A study of Mus musculus with 2 samples.

How the data were processed

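Gene expression was measured in 2 samples of the granule cell layer of the cerebellum of 8-week-old male C57BL/6J mice. The granule cell layer is the inner layer of the cerebellar cortex, which holds mostly granule neurons. Per the labels' protocols, brains were snap-frozen and cut sagittally at 12 μm, the layer was collected by laser capture microdissection, and about 1 ng of total RNA was amplified and biotin-labelled in 2 cycles for Affymetrix GeneChips. The titles of both samples name animal 1, and whether they come from 1 or several animals is not stated otherwise. They are called sample 1 and sample 2 here. The SD between them may therefore be technical and is not read as the spread between animals. The design text also names Purkinje cells, which were not analysed here.

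The authors deposited 1 signal intensity per probe set and array, on a linear scale. Per the submitters' processing notes these came from GCOS, the Affymetrix operating software. Its version, algorithm settings and scaling target are not given in the sources used here. The table held 45101 probe sets, 64 of them control probe sets. It held no detection calls, so the presence of a transcript was judged against genes that are not expected in the cerebellum. The median intensity was 7.9 in sample 1 and 8.3 in sample 2, and the mean after trimming 2% at each end was 44.9 and 46.5, a ratio of 1.04. The values were used as deposited, with no further scaling. Log2 values were planned, and the treatment of zeros was chosen after they were seen. The 2 zero values of sample 1 and the 1 zero value of sample 2 were set to 0.1, the smallest step of the table, before taking log2.

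Probe sets were named from the platform's annotation. It gave 1 gene symbol for 34958 probe sets and several for 932, and did not list 9211, which stayed unnamed here. Of the probe sets with 1 symbol, 34754 matched the RefSeq gene table by gene ID. A gene was represented by its brightest probe set over both samples, which gave 18194 named genes. The annotation is for the array's design and gives no probe positions. No genome coordinates were used.

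Choices were fixed before the data were examined. These were the 24 gene lists, the background list of 82 genes typical of other organs (71 measured, 104 probe sets), the thresholds and the rule for named genes. The background threshold of a sample was the 95th percentile of the background genes, an intensity of 14.3 in sample 1 and 18.8 in sample 2 (10.1 and 14.9 for probe sets). A gene above it in both samples is called above background. By construction a few background genes exceed it. In both samples 3 of 71 did, a keratin gene Krt10, the inhibin gene Inha and the trefoil factor gene Tff1. Of the 347 genes on the 24 lists, 304 were measured. A list was described by how many of its members were above background. The difference between the samples was taken as the median log2 difference of the members above background in at least 1 sample. It was set against 10000 random lists matched on intensity in 10 bins. A list is called outside when it fell beyond the central 95% of the random lists. Lists with under 3 such members were not compared.

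With 1 group of 2 samples, no test between groups was possible, and no p-value is given for any gene or list. The one probability given, among the closing observations, is for the number of lists outside their random lists. All values are descriptions of these 2 arrays, and their number limits the precision. Intensities of different probe sets depend on probe affinity and on distance from the 3′ end, so intensities of different genes are not read as their relative abundance. The place of a list's median intensity among random lists rests on such a comparison and is not reported, although it was planned. On simulated arrays with the measured spread, run over 18194 genes, 79% of 100 genes changed by 1.5 on the log2 scale and 98% of 100 genes changed by 3 passed 2-fold in the right direction. Of 7923 unchanged genes compared, 23.2% passed 2-fold. The spread was taken from these same arrays, so that share says nothing about the measured differences. Of 40 simulated lists of 14 genes shifted by 0.5, 80% fell outside the central 95%, against 2.5% of 40 unshifted lists. The simulated noise was independent between probe sets, and the lists held random genes above background in both samples. The measured lists were not built so, and these shares may not hold for them.

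The genes to be named were every measured granule neuron gene, and up to 4 members with the highest and 2 with the lowest mean log2 intensity of each other list. They also included Xist and the Y-linked genes, the Gapdh and Actb controls, the 10 genes with the largest difference between the samples in each direction whose probe sets above background went the same way, and the 20 genes with the highest intensity. The text gives the values that describe each list. Genes named outside this rule are marked as such. Alternatives were quantile and median scaling, thresholds at the 90th and 99th percentile, 39 olfactory receptor genes as background, the mean of all probe sets of a gene, probe sets ending in _x_at or _s_at left out, log2(value + 16), no background filter, and each sample alone. For the list differences, only members above background in both samples, and only members on no other list, were added after the data were seen. The analysis used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.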

Results

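Gene expression profiles were obtained from 2 laser-captured samples of the granule cell layer of the mouse cerebellum. Both titles name animal 1, which leaves open whether 1 or several animals were used. Each array gave an intensity for 45101 probe sets. Of the 45037 probe sets that were not controls, 15147 (33.6%) exceeded the background threshold in both samples. Of 18194 named genes, 7963 (43.8%) were above background in both. A further 1258 genes passed only in sample 1 and 613 only in sample 2. The threshold was lower in sample 1 (14.3) than in sample 2 (18.8). These 2 counts are therefore not read as more genes expressed in sample 1. Values below are mean intensities in array units ± SD over the 2 samples (n = 2). At a threshold set by the 99th percentile of the background genes, 4114 genes were above background.

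Markers of granule neurons, the small glutamatergic neurons that fill this layer, were almost all present. Of 23 measured markers, 22 were above background. Of the 23 genes, 8 were also on another list, such as those of receptors and channels. Gabra6, the GABA-A receptor subunit typical of cerebellar granule neurons, had an intensity of 8258 ± 97.3. Zic1, a zinc finger transcription factor of the cerebellar granule lineage, had 6754 ± 53.6. The proneural factor Neurod1 reached 4066 ± 326. The synaptic organiser Cbln1 reached 4469 ± 113 and its relative Cbln3 3480 ± 472. Cadps2, which takes part in dense-core vesicle release, had 4471 ± 470. The neuronal nuclear protein gene Rbfox3 had 2843 ± 105, the Rac GTPase-activating gene Chn2 2844 ± 126 and the calcium sensor Vsnl1 2725 ± 39.8. The same list held the extracellular matrix gene Reln (1711 ± 326), the potassium channel Kcnd2 (1452 ± 65.4), the vesicle calcium sensor Syt1 (1336 ± 50.3), the priming factor Unc13c (1021 ± 172), the calcium-binding protein gene Calb2 (883 ± 41.9) and the extrasynaptic GABA-A subunit Gabrd (650 ± 55.3).

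The remaining granule neuron markers above background were the cadherin Fat2 (369 ± 88.8), the NMDA receptor subunit Grin2c (167 ± 28.1), and the transcription factors Zic2 (126 ± 5.23), Neurod2 (122 ± 24.3), Pax6 (113 ± 43.8) and Meis1 (83.0 ± 20.1). Slc17a7, the vesicular glutamate transporter VGLUT1, had 20.7 ± 2.47, measured by its 1 named probe set, against thresholds of 14.3 and 18.8. Meis2 was the member that did not pass in both samples, with 21.7 ± 22. Probe sets of 1 gene often disagreed. Of the 199 listed genes with at least 2 probe sets, 97 (48.7%) had some above and some below background, as had 50.1% of all 9012 such genes. Pax6 passed with 2 of 5 probe sets, and Kcnd2 with 3 of 4.

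**Figure D1:**
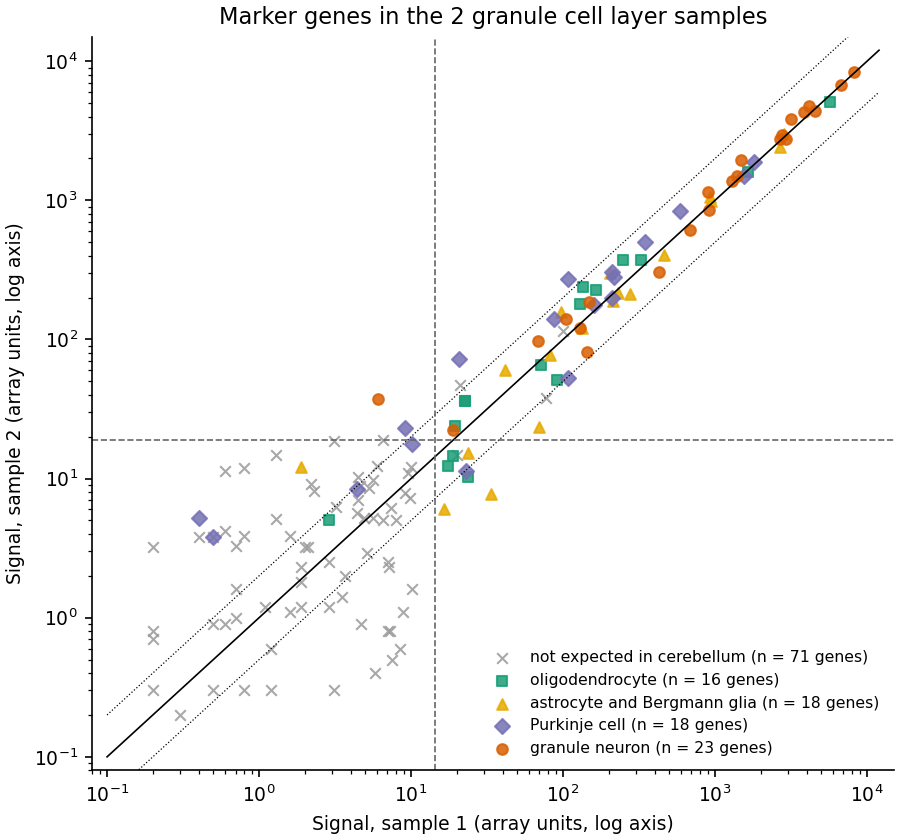
Intensity of each measured gene in sample 1 (x) and sample 2 (y), in array units on log axes, for the granule neuron, Purkinje cell, astrocyte and oligodendrocyte markers and the background genes; the solid line is equality, dotted lines are 2-fold differences, dashed lines the background thresholds of 14.3 and 18.8. The 22 granule neuron genes above background lie near equality, while background genes scatter widely.

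Markers of other cerebellar cell types were also detected. Of 18 measured Purkinje cell genes, 12 were above background. The phospholipase gene Plcb4 had 1843 ± 62.1, the aldolase gene Aldoc 1529 ± 30.5, the Notch ligand Dner 710 ± 175 and the calmodulin-binding protein gene Pcp4 425 ± 113. The homeobox gene Lhx5 (2.80 ± 3.39) and Plcb3 (2.15 ± 2.33) were below threshold. Chosen after their values were seen, the Purkinje markers Pcp2 (168 ± 12.6), Calb1 (204 ± 8.98) and Car8 (250 ± 45.5) were above background, while the glutamate transporter Slc1a6 was not (6.40 ± 2.83). Of the 18 genes, 3 were also on another list, as were 0 of the astrocyte and 2 of the oligodendrocyte genes described next.

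Glial transcripts were present. In the astrocyte and Bergmann glia list 14 of 18 genes were above background. These included the secreted chaperone Clu (2904 ± 111), the gap junction gene Gja1 (2554 ± 191), the glutamine synthetase gene Glul (991 ± 94.5) and the water channel Aqp4 (968 ± 39.6). The Bergmann glia marker Gdf10 (11.3 ± 7.5) and the GABA transporter Slc6a11 (7.05 ± 7.28) did not pass. Of 16 oligodendrocyte genes, 12 passed, among them the myelin genes Mbp (5428 ± 416), Cnp (1628 ± 25.5) and Mobp (308 ± 86.9), and the transcription factor Olig1 (351 ± 33.2). Opalin (14.9 ± 3.54) and Olig2 (3.95 ± 1.48) did not. With the 99th percentile threshold the oligodendrocyte count was 7.

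Of 13 GABAergic interneuron genes 6 passed, among them the GABA-synthesising enzyme Gad1 (259 ± 62.6), Lgi2 (256 ± 0.0707) and the vesicular GABA transporter Slc32a1 (102 ± 19.9), while the neuropeptide gene Npy (4.80 ± 4.38) and the receptor Kit (0.900 ± 0.566) did not. With the mean of all probe sets this count was 2. In the list for unipolar brush cells, glutamatergic interneurons of this layer, Eomes (105 ± 14.6) and Calb2 were above background, and Lmx1a (2.55 ± 3.18) was not; sample 1 alone gave 4 of the 5 genes. Of 15 endothelial and pericyte genes 9 passed, with the glucose transporter Slc2a1 at 747 ± 61.9 and Itm2a at 387 ± 10.2. The endothelial adhesion genes Cdh5 (5.85 ± 3.89) and Pecam1 (0.650 ± 0.212) did not. Of 13 microglial genes 4 passed, namely the receptor Csf1r (331 ± 113), the protease Ctss (265 ± 67.5), the complement gene C1qb (92.2 ± 40.7) and Tyrobp (41.1 ± 21.5). Aif1 (2.25 ± 2.76) and Itgam (0.400 ± 0.141) did not. At the 99th percentile threshold the endothelial and pericyte count was 5 and the microglial count 2.

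Markers of choroid plexus, meninges, blood and oligodendrocyte precursors were mostly at background. In the choroid plexus and meninges list 1 of 12 genes passed, the prostaglandin synthase Ptgds (1250 ± 28.2), and the choroid plexus marker Ttr had 2.80 ± 3.68. Of 6 blood cell genes 1 passed, the erythrocyte anion exchanger Slc4a1 (29.0 ± 9.12), and the globin gene Hba-a1 had 6.05 ± 0.778. Of 6 oligodendrocyte precursor genes only Sox10 (29.3 ± 9.55) passed. Each of these 3 lists rests on few genes. The blood count was 0 at the 99th percentile threshold, with the mean of all probe sets, and without _x_at and _s_at probe sets. The precursor count was 0 at the 99th percentile threshold and with the mean of all probe sets. The choroid and meninges list had 2 members above threshold in either sample alone, the blood list 2 in sample 2 alone, and the precursor list 2 in sample 1 alone and 3 in sample 2 alone.

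**Figure D2:**
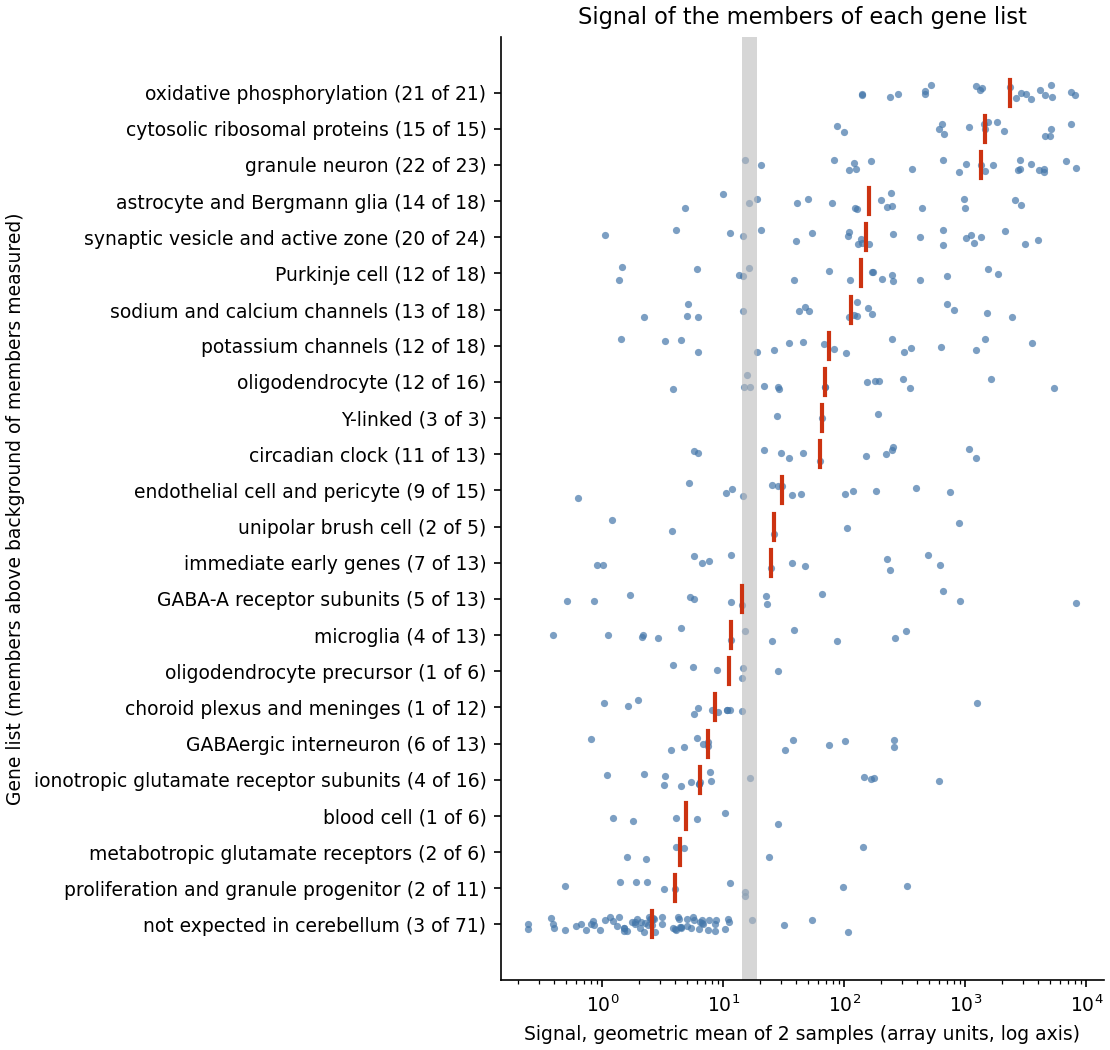
Each point is a gene's intensity (geometric mean of both samples, array units, log axis) within its list, with the red bar at the list median and the grey band spanning the background thresholds of 14.3 and 18.8. Granule neuron, ribosomal protein and oxidative phosphorylation genes lie almost wholly to the right of the band. The 71 background genes set the band, so by construction they lie almost wholly at or to the left of it.

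Of 13 GABA-A receptor subunits 5 were above background, including Gabra6, Gabrb2 (895 ± 57.1), Gabrd and Gabrb1 (67.8 ± 25.5). Gabra5 (1.90 ± 2.40) and Gabrq (0.750 ± 0.778) were not. Of 16 ionotropic glutamate receptor subunits 4 passed. They were the AMPA receptor subunits Gria2 (616 ± 155) and Gria4 (174 ± 7.64), the NMDA receptor subunit Grin2c and the kainate receptor subunit Grik2 (144 ± 3.18). The NMDA receptor subunit Grin2a (2.15 ± 2.62) and the kainate receptor subunit Grik4 (3.20 ± 3.25) were below threshold. Of 6 metabotropic glutamate receptors 2 passed, Grm4 (145 ± 47.4) and Grm3 (23.8 ± 0.495). With the mean of all probe sets, the GABA-A count was 3 and the ionotropic glutamate count 2, and with the 99th percentile threshold the metabotropic count was 1.

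Of 18 potassium channel genes 12 were above background, among them Kcnc1 (3556 ± 67.2), Kcnd2, the two-pore channel Kcnk1 (1231 ± 27.4) and Kcna1 (632 ± 135). Kcna4 (1.5 ± 0.707) and Kcna6 (3.30 ± 0.707) were not. Of 18 sodium and calcium channel genes 13 passed, among them Scn2b (2444 ± 282), Scn2a (1511 ± 262), Cacnb4 (809 ± 113) and Scn1a (704 ± 103), whereas Scn4b (5.0 ± 0.283) and Cacna1h (3.80 ± 4.38) did not. In the synaptic vesicle and active zone list 20 of 24 genes passed. Snap25 had 3980 ± 402, Rab3a 3105 ± 88.0 and Cplx1 2130 ± 53.3. Unc13b (5.10 ± 4.38) and the vesicular glutamate transporter VGLUT2 gene Slc17a6 (1.05 ± 0.0707) did not pass. With the mean of all probe sets the potassium channel count was 7 and the sodium and calcium channel count 8.

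Housekeeping lists were fully detected. All 21 oxidative phosphorylation genes and all 15 ribosomal protein genes were above background. Cox6a1 had 8096 ± 444, Cox7a2 7453 ± 36, Rps29 7523 ± 234 and Rps14 5117 ± 290. Ribosomal proteins have many processed pseudogenes, so their probe sets may pick up more than 1 transcript. The genes named for their high signal, which also depends on their probes, included Hint1 (8973 ± 200), the chaperone Hspa8 (8662 ± 87.7), Uqcrb (8658 ± 109), Stmn3 (6878 ± 381), Itm2b (6814 ± 388), Bex1 (6500 ± 385), Tuba1a (6424 ± 405), the imprinted gene Ndn (6409 ± 3.39), the histone gene H2az1 (6288 ± 195), Mapre2 (6214 ± 488) and Gpm6a (6131 ± 356).

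Of 11 proliferation and granule progenitor genes 2 were above background, the hedgehog receptor Ptch1 (331 ± 24.9) and Ccnd1 (98.0 ± 3.68). The mitotic kinase gene Cdk1 (0.550 ± 0.354) and Mycn (1.40 ± 0.283) were below threshold. Of 13 immediate early genes 7 passed, among them Fos (616 ± 109), Dusp1 (499 ± 152), Jun (237 ± 20.7) and Egr1 (223 ± 8.27), and Fosb (1.15 ± 0.778) and Egr2 (2.10 ± 2.69) did not. Of 13 circadian clock genes 11 passed, including Nr1d2 (1240 ± 179), Dbp (1067 ± 111), Rora (258 ± 69.3) and Cry1 (250 ± 39.2), while Nr1d1 (6.20 ± 1.27) and Npas2 (6.00 ± 2.55) did not. With the 99th percentile threshold the immediate early count was 4 and the clock count 6. With the 90th percentile threshold the proliferation and granule progenitor count was 4.

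The sex that the labels give, male, could be set against sex-linked transcripts. The Y-linked genes Eif2s3y (193 ± 33.2), Kdm5d (65.1 ± 5.09) and Uty (29.2 ± 12.4) were above background in both samples. Xist, which is expressed from the inactive X of females, was at 5.6 ± 6.36 and Tsix at 0.550 ± 0.212, both below threshold in both samples. At the 99th percentile threshold 1 of the 3 Y-linked genes passed, and with the mean of all probe sets 0 did.

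The granule neuron list as a whole differed little between the samples. Its median log2 difference (sample 1 minus sample 2) was −0.09, at percentile 27.8 of matched random lists. Of the 23 genes, 8 were higher in sample 1 and 15 in sample 2. Single members differed more, such as Pax6 (0.81) and Meis2 (−2.61), which was not above background in both. The median over the 15147 probe sets above background in both was −0.095, so the lean toward sample 2 was not particular to this list. Over the 15147 probe sets above background in both, Pearson's r of the log2 intensities was 0.928 and Spearman's rho 0.879, across probe sets, which are not independent replicates. The SD of the log2 difference was 0.71, and 84.2% of the probe sets were within 2-fold. Agreement rose with intensity. All 801 probe sets of 1000 or more were within 2-fold, with an SD of 0.19. Between 100 and 1000 the share was 94.5% of 4870 and the SD 0.50, between 20 and 100 it was 73.4% of 8442 and 0.96, and under 20 it was 40.9% of 30924 and 2.17. Without a background filter r was 0.806.

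Of 9834 genes above background in at least 1 sample, 1104 were at least 2-fold higher in sample 1 and 1102 in sample 2, together 22.4%. These counts depended on the processing. They were 258 and 408 at the 99th percentile threshold, 452 and 526 with log2(value + 16), and 3332 and 3515 with no background filter. Among genes above background in both, the largest differences toward sample 1 were those of the kinase gene Mapk12 (274 against 38.1, a log2 difference of 2.85), Tmem255a (137 against 24.3, 2.49), Lyrm2 (126 against 26.1, 2.27), Osgepl1 (2.25), Gtf2e2 (2.25), Frmd4b (2.23), Mthfd2l (2.19), Pogk (2.13), Yrdc (2.13) and Atp13a4 (2.07). The largest toward sample 2 were those of Pcgf6 (27.4 against 208, −2.92), Dpcd (−2.73), Rhno1 (−2.61), Zfp267 (−2.60), Pus3 (−2.55), the mitochondrial polymerase subunit Polg2 (69.6 against 408, −2.55), Ccl27a (−2.50), the protease Ctsc (−2.49), Dsel (−2.43) and the calcium channel Cacna1d (−2.39). Of these 20 genes, Mapk12 and Lyrm2 had 2 probe sets above background and the others 1, so the direction of the others has no second measurement. The probe sets of Cacna1d, Pogk and Ccl27a are of the _s_at or _x_at kind, which can match several transcripts, and the other probe sets of Cacna1d (2.57) and Pogk (5.94) were below background. Several of the lower values lay near the background threshold. In sample 1, with a threshold of 14.3, these were Dsel (15.1), Pus3 (15.6), Ctsc (17) and Zfp267 (18.1). In sample 2, with a threshold of 18.8, Atp13a4 was at 19.1. With 1 sample on each side the differences of all these genes have no replicate check.

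Of the 22 gene lists that could be compared between the samples, 2 fell outside the central 95% of matched random lists, and chance gives 1.1. The Purkinje cell list had a median log2 difference of −0.44, lower in sample 1, at percentile 0.49. Of its 14 members compared, 10 were lower in sample 1 and 4 higher. The shift was uneven, as members chosen after their values were seen show. Plcb4 (−0.07), Aldoc (0.04), Pcp2 (−0.15) and Calb1 (0.09) differed little. Ppp1r17 (−1.81), Rgs8 (−1.34) and Cacna1g (−1.34, not above background in both) were much lower in sample 1. Pvalb (1.02) and Foxp2 (1.01, not above background in both) were higher. The sodium and calcium channel list had −0.33 at percentile 2.46, with 12 of 14 members lower in sample 1. It lay inside under quantile normalization, both other thresholds, the olfactory receptor background, no filter, the mean of all probe sets and the omission of _x_at and _s_at probe sets, at percentiles of 2.64 to 9.09. The Purkinje cell list lay outside under every alternative that was run for it.

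**Figure D3:**
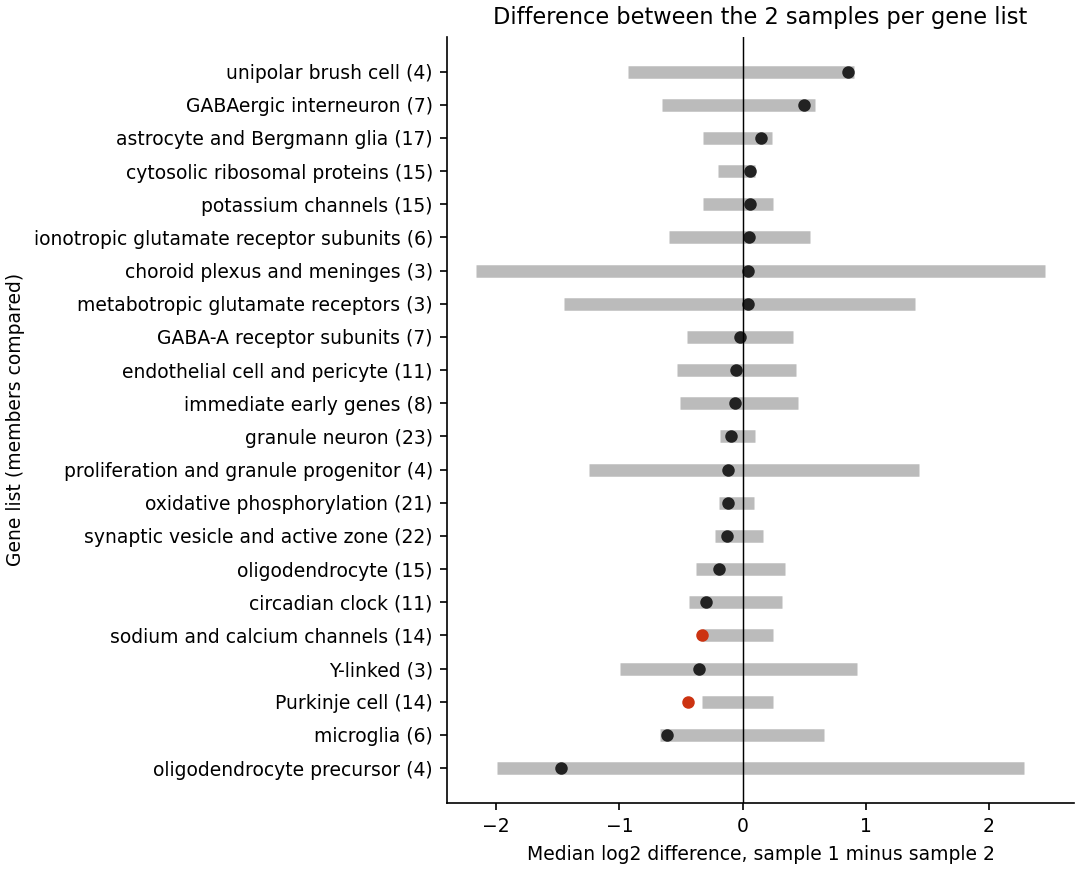
Median log2 difference between the samples (sample 1 minus sample 2) per gene list, as points, with grey bars for the central 95% of 10000 random lists matched on intensity; the number of members compared is in parentheses. The Purkinje cell list at −0.44 and the sodium and calcium channel list at −0.33, in red, lie outside their bars.

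Control probe sets for both ends of a transcript were compared. For Gapdh the 3′ probe set was 10.3 ± 0.231 times as bright as the 5′ probe set, and for Actb 33.4 ± 6.29 times. For 18S ribosomal RNA, which carries no poly-A tail, the ratio was 0.810 ± 0.10. The bacterial poly-A control transcripts, which are added to total RNA before labelling where the manufacturer's kit is used, had ratios from 9.75 to 54.0 over 8 probe set pairs in 2 samples. The hybridization controls, which are added after labelling, had ratios from 0.945 to 1.28 over 4 pairs. Probe sets at the 2 ends differ in affinity, so a ratio is not a direct measure of length. The TrpnX control probe sets gave intensities of 0.4 to 5.5 in both samples.

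**Figure D4:**
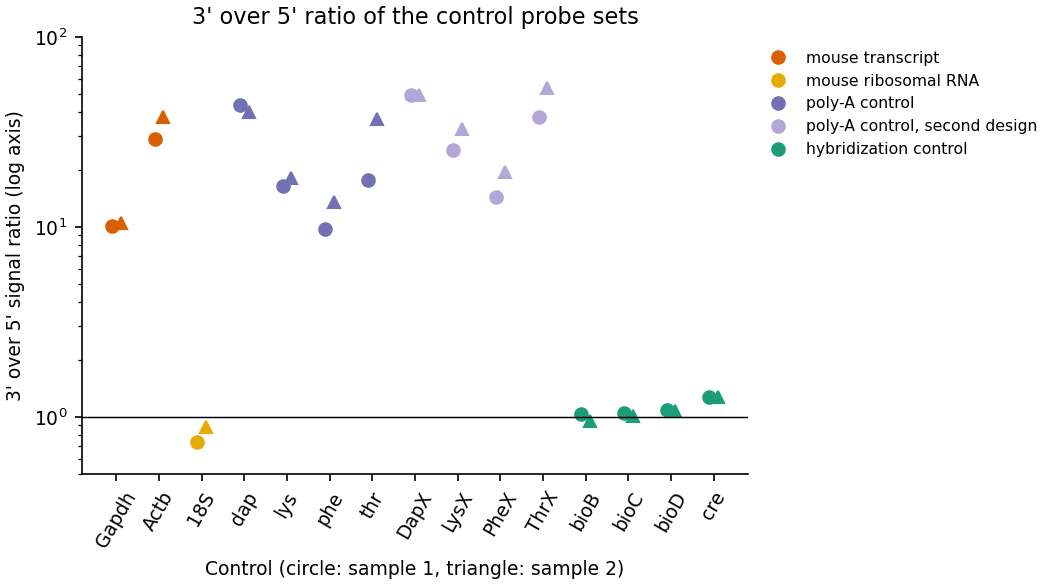
Ratio of 3′ over 5′ intensity (log axis) of each control in sample 1 (circles) and sample 2 (triangles), coloured by kind of control. Gapdh, Actb and the poly-A controls lie between 9.75 and 54.0, and the hybridization controls lie between 0.945 and 1.28.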

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

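The tests restricted to list members above background in both samples, or to members on no other list, were chosen after the results were seen. Over the main counts and correlations, 265 values under alternatives stayed within 1.5 times the reported count or within the stated spread, and 48 moved beyond it. Over the other values these numbers were 1590 and 247, and 1 reversed. Under quantile normalization and median scaling all 24 list counts stayed within 1.5 times. The 99th percentile threshold left 6696 probe sets and 4114 genes above background, 258 and 408 genes at least 2-fold higher in samples 1 and 2, and r of 0.950. List counts were then 3 for GABAergic interneurons, 7 for oligodendrocytes, 0 for their precursors, 2 for microglia, 5 for endothelial cells and pericytes, 0 for blood, 3 for GABA-A subunits, 1 for metabotropic glutamate receptors, 4 for immediate early, 6 for clock and 1 for Y-linked genes. The 90th percentile gave 2 for choroid plexus and meninges and 4 for proliferation and granule progenitors. The olfactory receptor background gave 4 for choroid plexus and meninges, 2 for blood and 5 for proliferation and granule progenitors. It also gave 1685 and 1691 genes at least 2-fold higher in samples 1 and 2, and r of 0.924. The mean of all probe sets gave 2 for GABAergic interneurons, 0 for oligodendrocyte precursors, 0 for blood, 3 for GABA-A and 2 for ionotropic glutamate subunits, 7 for potassium channels, 8 for sodium and calcium channels, 7 for clock and 0 for Y-linked genes. With log2(value + 16), 452 and 526 genes were at least 2-fold higher in samples 1 and 2 and r was 0.946, and with no background filter 3332 and 3515 were and r was 0.806. In each sample alone the counts ranged from 2 to 4 for unipolar brush cells, 2 to 3 for oligodendrocyte precursors and 1 to 2 for blood, and were 2 for choroid plexus and meninges. Without _x_at and _s_at probe sets the blood count was 0. Cacna1d is then represented by a probe set below background (2.57), whose difference of 1.75 has the opposite sign but measures no expression. The number of lists outside the random lists was 1 under quantile normalization and 1 without _x_at and _s_at probe sets, since the sodium and calcium channels then lay inside. Those channels also lay inside with only members above background in both samples (percentile 4.26) and only members on no other list (4.05). The microglial list, at percentile 3.32, lay outside with the 99th and 90th percentile thresholds, log2(value + 16) and the mean of all probe sets (1.42 to 2.36), and lay at 84.6, higher in sample 1, without _x_at and _s_at probe sets. The oligodendrocyte precursor list lay outside with the 90th percentile threshold and the olfactory receptor background, the GABAergic interneuron list with only members above background in both samples, and the unipolar brush cell list with no filter and with only members on no other list. The cause of the other shifts was not tested, beyond the threshold, members or background genes that each alternative itself changes. No paired analysis was possible because there is only 1 group. Below an intensity of 20, 40.9% of probe sets were within 2-fold, which limits what single dim genes show.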

Other observations

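All tests in this part were chosen after the results they address were seen, and only the genes of the second Purkinje list were fixed before their own values were seen. The 10 gene families described first were picked by symbol after seeing the data. They differed in how many members were above background. All 4 measured Zic transcription factors passed, with Zic5 at 257 ± 28.7 and Zic4 at 32.5 ± 14.2 beside Zic1 and Zic2. All 4 nuclear factor I genes passed as well, with Nfix at 1050 ± 110, Nfib at 697 ± 63.6, Nfia at 514 ± 42.9 and Nfic at 67.5 ± 5.52. Of 33 Hox genes, transcription factors of more posterior body regions, only Hoxa5 (63.6 ± 4.03) passed, through an _x_at probe set while its other one read 0.990, and 0 passed without such probe sets, and none of 13 serotonin receptor genes did. Of 19 Wnt ligand genes only Wnt7a (316 ± 89.6) passed.

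Of 9 measured genes for calmodulin-dependent kinases and their activating kinase 7 passed, with the nuclear kinase Camk4 at 2477 ± 27.4 through 1 of its 5 probe sets and its activator Camkk2 at 3098 ± 126. The median log2 difference of the family was −0.63, lower in sample 1, at percentile 0.76 of matched random lists, with 5 members lower in sample 1 and 2 higher. Camk4 (0.02) and Camkk2 (−0.08) differed little, Camk2b (−0.63), Camk1 (−0.70), Camk2d (−0.74) and Camk2g (−0.99) were lower in sample 1, and Camk1d (0.47) was higher. It was the 1 family outside the central 95% among 7 compared, and the others lay inside. Chance gives 0.35 for families picked beforehand. These families were picked after the data were seen, so 0.35 is no yardstick for the 1 found. Of 4 FGF homologous factor genes, which bind sodium channels, 3 passed, with Fgf12 at 697 ± 74.2 and Fgf14 at 589 ± 110. Of 13 Eph receptor genes 3 passed, including Ephb1 (195 ± 14.6), of 20 semaphorin genes 11 passed, including Sema4f (617 ± 20.6) and Sema6d (225 ± 41.8), and of 22 protocadherin beta genes 7 passed. Of the 9160 probe sets without annotation that were not controls, 1444 (15.8%) were above background, against 38.0% of those with 1 gene symbol.

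The 5′ probe sets of Gapdh and Actb were far dimmer than their 3′ probe sets. An array or hybridization that favours 3′ probe sets in general is argued against by the hybridization controls, whose highest ratio was 1.28. Shortening from the 5′ end in the 2 rounds of amplification is consistent with the poly-A controls, which carry no tissue history and whose lowest ratio was 9.75. Degraded tissue RNA as a further cause stays open, since all 4 ratios of Gapdh and Actb lay within the range of those controls. The 18S ratio of 0.810 went the other way and was not weighed, because that RNA carries no poly-A tail; no biological explanation was tested.

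Purkinje cell, astrocyte and oligodendrocyte genes, such as Plcb4 (1843), Clu (2904) and Mbp (5428), were above background in tissue captured as granule cell layer. Chance passing of unexpressed probe sets was examined with 39 olfactory receptor genes, which did not set the threshold and are taken as unexpressed. In both samples 0% of them passed, against at least 66.7% of the members of each list and 43.8% of all genes. The threshold was set high among genes taken as unexpressed, so a low share was likely beforehand. The number of probe sets per gene, of which the brightest was used, was not matched. The values show that the threshold held for a second set of such genes, and do not decide on single markers. Of 18 choroid plexus, meninges and blood markers 11.1% passed, Ptgds at 1250 and Slc4a1 at 29.0. The abundant choroid plexus transcript Ttr was at 2.80 and the 1 globin gene measured here, Hba-a1, at 6.05. These values describe how few of those markers were detected. They cannot decide where the Purkinje cell, astrocyte and oligodendrocyte RNA came from, because those genes were listed as markers of other cells. RNA of glia inside the layer, of neighbouring Purkinje cells and white matter, and of granule neurons that share these genes stays open and untested, because no capture of another layer was analysed here.

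The Purkinje cell list was lower in sample 1 than in sample 2, and its 11 compared members on no other list lay at percentile 2.27, but that value was computed first, on genes that show the pattern, and does not bear on its cause. A candidate explanation is more Purkinje cell RNA in the second capture. A second list of 12 Purkinje genes was then written, of which 11 were measured, 6 compared and 3 lower in sample 1, with a median difference of −0.06 at percentile 36.8, which leaves it open. Camk2a, one of the listed genes, belongs to the calmodulin-dependent kinase family, whose median had been seen. Spread between arrays over the 22 lists compared also stays open, since at least 2 lists outside would arise with probability 0.302 if the lists were independent and unshifted; no biological explanation was tested.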
